A study of Homo sapiens with 14 samples.

How the data were processed

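ATAC-seq peak lists of 14 libraries of primary human NK cells were used, 1 list per library. The labels give a transposase reaction on isolated NK cell nuclei and paired-end sequencing. How NK cells were separated from AML cells before that reaction is not given in the sources used here. Bowtie2, MACS2 and deepTools and the genome build hg19 are named in the submitters' processing notes, without versions. Whether reads were shifted for the transposase or duplicates removed is not given in the sources used here, and both can move peak edges and heights.

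Each deposited list gives the position, a score, a fold enrichment, a −log10 p, a −log10 q and a summit offset for each peak. The deposited score is 10 times the −log10 q for almost all peaks and was not used. The deposited fold enrichment, a ratio of peak height to local background, is the authors' own value for each peak and was used only to describe named regions. The deposited −log10 q values start between 1.30 and 1.34 in every list, and were used to rank and filter peaks within a list. Peaks were called per library, as there is 1 list per sample. Peaks on chromosomes 1 to 22 and X were used.

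Groups were taken from the labels. The design text and a sample title differ on the NK source of 1 knockout direct library, and the title was followed. The labels give the NK source of each library, which pairs libraries across groups by source; the differences between the sources in 10 pairs of groups correlated at 0.0136 to 0.116 over regions. Replicates of a group differ in NK source or AML label, so the spread between them holds both. The p-values between groups rest on 2 to 4 libraries per group. Sets that pool groups hold 4 to 10 libraries and mix genotypes, culture types or both.

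All peaks were merged into regions where they overlapped by at least 1 bp. A region was gained where every library of the first group and no library of the second had a peak, and lost in the reverse case. The sum of both was compared with that of all other splits of the same libraries, or 100 drawn with a fixed seed where there were more. Numbers of peaks and shares were compared by exact permutation tests and similarity by one-sided exact permutation. Benjamini-Hochberg adjustment ran over the 7 planned comparisons of each measure. The design and its alternatives were fixed before the data were examined. These were a −log10 q of at least 5, the 43859 strongest peaks of each library, cover of at least 50% of a region, 501 bp summit windows, each library left out in turn, co-cultures of the first AML label only, and permutation within NK source.

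Named regions were chosen by a fixed rule. A strong gain had a peak in every library of the first group, each among the 43859 strongest of its list, and none in the second group, and strong losses were the reverse. They were ordered by the worst rank percentile within a list. The first 10 per direction are printed for Cas9 direct co-culture against alone and the first 3 for other comparisons. Starts are 1-based. The gene table at hand is of another genome build and no hg19 sequence was at hand, so genes near regions, promoters, transcription factor motifs, gene lists, cell type markers and the TGFBR2 and BATF loci were not analysed here. Peaks at the TGFBR2 locus would not have checked the knockout, and no other check of it was made.

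Depth was judged from the peak heights. In a list made without a control, the fold and the −log10 p together fix a whole number of reads and a background, and a whole number was recovered for 100% of peaks in every list, to within 0.001 in −log10 p. The most frequent background in a list was taken as its relative depth, from 0.769 to 2.01 reads. For a region found in 1 set of libraries, the least height among them was scaled to another library by the median height of regions shared by all 14. The region was expected above that library's limit where it would pass the lowest −log10 p of the list with a probability of 0.95. Between replicates of a group, 85.4% to 96.1% of regions expected by this rule had a peak, and 28.1% to 52.6% of the others. The least height is the stricter choice.

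The functions were tested on simulated peak lists for Cas9 direct co-culture against alone. All 200 seeded gains and 200 seeded losses among 82474 regions were recovered, with 599 other gains where chance gives 623. Merged regions had 0 differences from those of bedtools 2.31.1, and 100% of 20000 simulated heights were recovered. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.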

Results

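Chromatin accessibility was measured by ATAC-seq, which tags open chromatin with a transposase, in 14 libraries of primary human natural killer (NK) cells. Cells carried Cas9 only (the control) or a knockout of TGFBR2, a receptor subunit for transforming growth factor beta. They were cultured alone, together with acute myeloid leukaemia (AML) cells in direct contact, or with AML cells across a transwell membrane, which keeps the cells apart. The 5 groups held 2 Cas9 libraries cultured alone, 3 Cas9 direct co-cultures, 3 Cas9 transwell co-cultures, 2 knockout libraries cultured alone and 4 knockout direct co-cultures. NK cells came from 2 sources and AML cells carried 2 sample labels. The series title names the transcription factor BATF and NK cell dysfunction in AML as its subject.

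The peak lists held 755592 peaks on chromosomes 1 to 22 and X, from 43859 in Cas9 transwell replicate 1 to 62666 in Cas9 direct replicate 2. Merging them gave 89504 regions, of which 32661 (36.5%) had a peak in all 14 libraries and 17132 (19.1%) in 1 library. The background coverage recovered from the lists, a measure of relative depth, ran from 0.769 reads in Cas9 transwell replicate 1 to 2.01 reads in Cas9 alone replicate 2. Transwell replicate 1 was thus the shallowest library, and regions missing from it are less certain than regions missing elsewhere.

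Direct co-culture libraries held the most peaks in both genotypes. Cas9 cells had 60699 ± 3332 peaks in direct co-culture (SD, n = 3), 49650 ± 6478 in transwell co-culture (SD, n = 3) and 48707 ± 6741 alone (SD, n = 2). Knockout cells had 56589 ± 2504 in direct co-culture (SD, n = 4) and 50388 ± 3263 alone (SD, n = 2). All 3 Cas9 direct libraries lay above both Cas9 libraries cultured alone and above all 3 transwell libraries, and all 4 knockout direct libraries lay above both knockout libraries cultured alone. The Cas9 direct against alone difference of 11992 peaks gave a two-sided exact permutation p of 0.1 with n = 3 and 2, the smallest this design allows (adjusted p = 0.175 over 7 comparisons). The knockout difference of 6201 peaks gave an exact permutation p of 0.0667, also the smallest possible for n = 4 and 2 (adjusted p = 0.175). Transwell and alone differed by 944 peaks, less than the spread between replicates (exact permutation p = 1, n = 3 and 2).

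**Figure D1:**
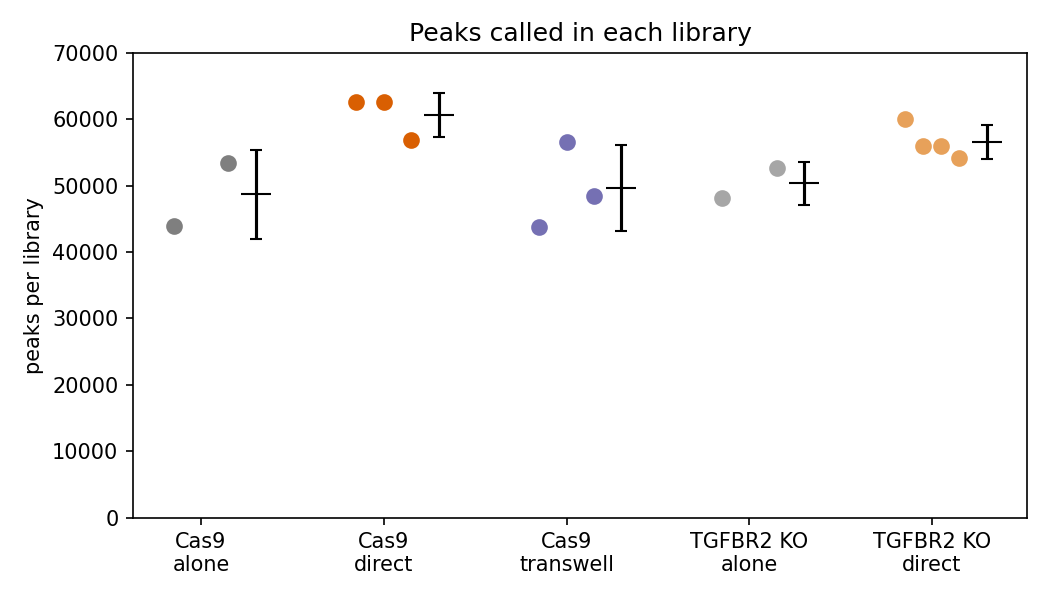
Peaks per library (vertical axis) for the 5 groups (horizontal axis); each point is a library, and the black line and bar give the group mean and SD. The 3 Cas9 direct libraries lie between 56852 and 62666 peaks, above the 2 Cas9 libraries cultured alone at 43940 and 53473.

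The comparison of Cas9 direct co-culture with Cas9 cells cultured alone asked where contact culture with AML cells went along with opened or closed chromatin. A peak in all 3 direct libraries and in neither library cultured alone was found in 4455 regions, and the reverse in 369, so 92.4% of the changed regions were gained. With every list shortened to its 43859 strongest peaks, 2091 regions were gained and 1542 lost, or 57.6% gained. Equal list lengths pull gains and losses towards balance by construction (7575 regions in Cas9 direct replicate 1 only and 7227 in Cas9 alone replicate 1 only, against 20489 and 2393 as deposited), so here and below the share gained under this setting does not show where an excess came from. Kept to regions expected above the limit of every library without the peak, 1963 were gained and 185 lost. The strongest gained region lay on chromosome 2 from 9692602 to 9693180 (hg19), with the authors' fold enrichment at 6.42 ± 0.454 (SD, n = 3). It was followed by chromosome 2 from 204751389 to 204751923 at 10.9 ± 0.808. Both had a peak in all 7 direct libraries of either genotype and in none of the other 7. Chromosome 3 from 192675107 to 192675893 stood at a fold of 17.9 ± 2.08, and chromosome 20 from 44572648 to 44573331 at 8.60 ± 0.564. Next came 2 regions of chromosome 1, from 59758309 to 59758715 at 6.89 ± 0.569 and from 197062514 to 197063202 at 24.8 ± 2.44, both of which also had a peak in all 3 transwell libraries. The remaining 4 of the first 10 gained regions were chromosome 3 from 138505570 to 138506062 (16.7 ± 2.84), chromosome 5 from 52106780 to 52107357 (18.2 ± 1.36), chromosome 11 from 72686730 to 72687538 (19.6 ± 2.71) and chromosome 20 from 49077236 to 49077667 (29.8 ± 2.76). The last of these had a peak in 2 of the 4 knockout direct libraries, and the other 9 in all 4. The region of chromosome 11 also had a peak in all 3 transwell libraries. Both regions of chromosome 3 had one in 2 transwell libraries, and both of chromosome 20 and that of chromosome 5 in 1. The regions of chromosome 11 and of chromosome 3 from 138505570 had a peak in 1 knockout library cultured alone.

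Strongly lost regions were fewer, 147 against 1596 strongly gained. The first was on chromosome 15 from 32954862 to 32955187, at a fold of 16.0 ± 0.367 in the 2 libraries cultured alone (SD, n = 2). Chromosome 14 from 50507140 to 50507567 stood at 6.10 ± 0.376, chromosome 3 from 124389932 to 124390321 at 12.7 ± 0.590, and chromosome 1 from 15946732 to 15946935 at 3.54 ± 0.382. Chromosome 3 from 112627043 to 112627642 stood at 12.5 ± 4.04, chromosome 19 from 31711441 to 31711901 at 11.9 ± 1.01, and chromosome 15 from 38978186 to 38978565 at 6.68 ± 0.502. The last 3 named were chromosome 6 from 15327508 to 15327768 (5.24 ± 0.244), chromosome 1 from 42269937 to 42270154 (4.38 ± 0.0196) and chromosome 5 from 55908542 to 55908974 (10.3 ± 2.40). The regions of chromosome 15 from 38978186 and of chromosome 5 from 55908542 had a peak in all 4 libraries cultured alone and in no co-culture. Others were less uniform: the first, on chromosome 15 from 32954862, had a peak in 3 of the 4 knockout direct libraries. The regions of chromosomes 14 and 6, of chromosome 3 from 124389932 and of chromosome 1 from 42269937 had one in all 3 transwell libraries. Among the 10 splits of the 5 libraries the real one separated the most regions, 4824, while the split that put Cas9 direct replicate 3 with the libraries cultured alone separated 4656, and 10 splits cannot give a share under 10%. Leaving out a library loosens the rule: gains rose to 8797 without Cas9 direct replicate 3 and 8930 without Cas9 alone replicate 2, and losses to 791 and 683 without Cas9 direct replicates 1 and 3 and to 2954 and 1099 without Cas9 alone replicates 1 and 2.

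**Figure D2:**
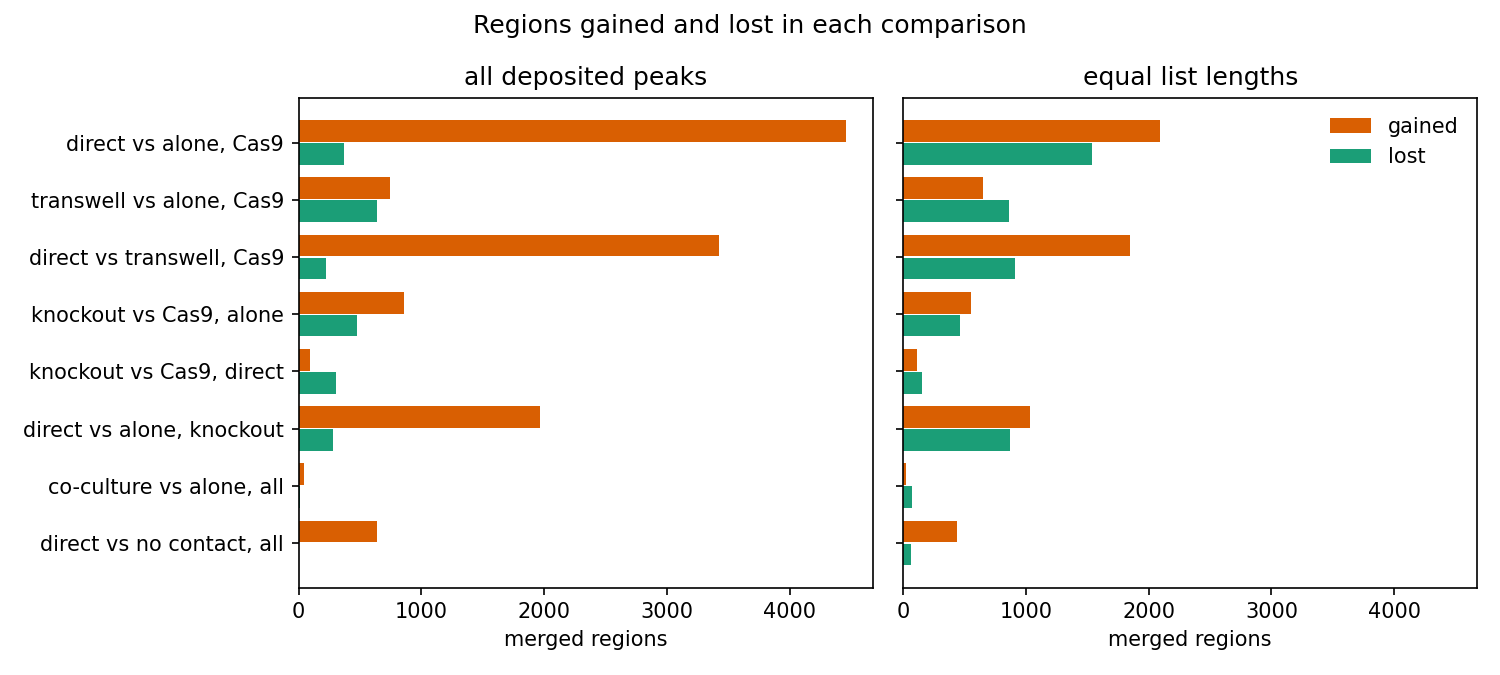
Merged regions (horizontal axis) gained (orange) and lost (green) in each comparison (vertical axis), from all deposited peaks (left) and from the 43859 strongest peaks of each library (right). Direct co-culture of Cas9 cells against alone gives 4455 gained and 369 lost on the left, and 2091 and 1542 on the right.

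Transwell co-culture of Cas9 cells, which asks what soluble signals go along with, separated fewer regions from culture alone: 742 were gained and 635 lost. With equal list lengths the numbers were 648 and 864, with shares gained of 53.9% and 42.9%. Among regions expected above the limit of every library without the peak, 466 were gained and 67 lost. This kept 62.8% of the gains and 10.6% of the losses, as the shallow transwell libraries are the ones that lack a lost peak, so neither setting tells whether gains or losses prevailed. The first 3 strongly gained regions were chromosome 10 from 76990443 to 76990670 (fold 5.30 ± 0.446, SD, n = 3), chromosome 1 from 244436250 to 244436765 (17.1 ± 1.87) and chromosome 17 from 7259414 to 7259616 (5.52 ± 0.446). Strongly lost were chromosome 9 from 92036983 to 92037749 (6.74 ± 0.744, SD, n = 2), chromosome 1 from 172796884 to 172797433 (11.7 ± 0.291) and chromosome 7 from 26195858 to 26196411 (6.78 ± 0.217). The first and the third of these losses had a peak in all 3 Cas9 direct libraries, so they were missing from the transwell libraries only. Of the 10 splits of the 5 libraries, 4 separated at least as many regions as the real one (1377), and the highest, 2742, was the split by NK source. Background coverage split the same way, at 0.769 to 1.41 reads in 1 source and 1.55 to 2.01 in the other. Source and depth thus cannot be told apart there. Within NK source the real split was the highest of 6 (1377 against 1277), and with equal list lengths the highest of 10 (1512 against 1379), where neither number of splits can give a share under 10%. Gains rose to 1926 and 1372 without Cas9 transwell replicates 1 and 3 and to 2871 without Cas9 alone replicate 2, and losses to 1999 without transwell replicate 2 and to 4156 and 1529 without Cas9 alone replicates 1 and 2, so that losses outnumbered gains without transwell replicate 2 (1081 gained) or Cas9 alone replicate 1 (1098 gained).

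Direct against transwell co-culture of Cas9 cells compares culture in contact with AML cells with culture across a membrane. The 2 groups are not matched: with the second AML label, the direct and the transwell library came from different NK sources. Contact and source cannot be told apart for that label. With the first AML label only, both groups hold both sources, and 8287 regions were gained and 923 lost with fewer libraries to match. Contact went with 3424 gained and 226 lost regions (93.8% gained), or 1850 and 909 with equal list lengths (67.1% gained). In pairs of the same NK source, Cas9 direct replicate 1 held 21664 regions missing from transwell replicate 1, with 3219 the other way. For direct replicate 1 and transwell replicate 3 the numbers were 18092 and 4197. Against transwell replicate 2, the deepest of the 3 (background 1.55 reads), Cas9 direct replicate 2 gave 14487 and 8282. Cas9 direct replicate 3 gave 8876 and 8681, so that pair was nearly even. The excess thus varied with the libraries paired. Of the 3424 and 226, 466 gains and 172 losses were expected above the limit of every library without the peak (73.0% gained). The strongest gains were again chromosome 2 from 9692602 to 9693180 and from 204751389 to 204751923, followed by chromosome 12 from 107723288 to 107723772 at a fold of 16.4 ± 1.09 (SD, n = 3). The strongest losses were chromosome 10 from 76990443 to 76990670 (5.30 ± 0.446, SD, n = 3), chromosome 4 from 48142932 to 48143292 (8.78 ± 0.151) and chromosome 1 from 10398045 to 10398534 (15.3 ± 5.14). The real split separated 3650 regions and the highest of the other 9 separated 876, but 10 splits cannot give a share under 10%. Gains were 7555 without Cas9 direct replicate 3 and 5838 without Cas9 transwell replicate 2; losses were 484, 359 and 493 without Cas9 direct replicates 1, 2 and 3, and 738, 362 and 506 without transwell replicates 1, 2 and 3.

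The knockout was compared with Cas9 cells in culture alone, where 860 regions were gained and 474 lost (550 and 466 with equal list lengths, with shares gained of 64.5% and 54.1%). Among regions expected above the limit of every library without the peak, 210 were gained and 210 lost. The first gained regions were chromosome 1 from 17222562 to 17222803 (fold 30.0 ± 1.43, SD, n = 2), chromosome 8 from 96260879 to 96261220 (16.9 ± 0.258) and chromosome 7 from 25138043 to 25138370 (13.4 ± 2.09). The first lost regions were chromosome 1 from 200108738 to 200109188 (17.0 ± 0.752, SD, n = 2), chromosome 3 from 169480807 to 169481093 (4.90 ± 0.197) and chromosome 4 from 151788142 to 151788687 (14.3 ± 0.894). In the same order, these losses had a peak in 4, 2 and 3 of the 4 knockout direct libraries. The named gains had one in 2, 1 and 1 of the 3 Cas9 direct libraries. Both other splits of the 4 libraries cultured alone separated more regions than the 1334 of the real one. The split by NK source separated 3680, and the other split within NK source 1451. Background coverage also split by source, at 1.41 and 1.57 reads against 1.75 and 2.01, so source and depth cannot be told apart here. Each library left out moved the counts: gains to 4907 and 2943 without knockout alone replicates 1 and 2 and to 4083 without Cas9 alone replicate 2 (1360 without Cas9 alone replicate 1), and losses to 1217, 1964, 4555 and 1518 without knockout replicates 1 and 2 and Cas9 replicates 1 and 2.

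In direct co-culture, where all 7 libraries had to match, 89 regions were gained and 301 lost in the knockout (22.8% gained). With equal list lengths the numbers were 112 and 152 (42.4% gained). Those expected above the limit of every library without the peak were 26 and 76. Gained regions were led by chromosome 15 from 48644755 to 48645107 (fold 13.5 ± 0.841, SD, n = 4), chromosome 5 from 96272451 to 96272696 (2.39 ± 0.177) and chromosome 11 from 61665183 to 61665541 (5.66 ± 0.422). Lost regions were led by chromosome 17 from 8798168 to 8798648 (8.03 ± 2.06, SD, n = 3), chromosome 1 from 161089545 to 161089869 (4.48 ± 0.213) and chromosome 6 from 154562316 to 154562612 (9.53 ± 1.58). The regions of chromosomes 17 and 6 had a peak in the 3 Cas9 direct libraries and in no other library. Of the 35 splits of these 7 libraries, 6 separated at least as many regions as the real one, so its 390 ranked sixth, above the median of 192 and far below the highest of 1840. Gains ran from 155 to 342 and losses up to 2194 when 1 library was left out, the highest of both without Cas9 direct replicate 3. Gains were 213, 155, 158 and 193 without knockout direct replicates 1, 2, 3 and 4, and 230 and 179 without Cas9 direct replicates 1 and 2. Losses were 826 without knockout direct replicate 1, and 603 and 504 without Cas9 direct replicates 1 and 2. With the first AML label only, where fewer libraries have to match, 956 regions were gained and 2873 lost. The low counts over all libraries thus depend on how many must match, and do not show that the genotypes were alike.

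Direct co-culture of knockout cells also went with more gained than lost regions against knockout cells alone, 1963 and 278 (87.6% gained), or 1035 and 875 with equal list lengths (54.2% gained). Those expected above the limit of every library without the peak were 993 and 86. The strongest gains were chromosome 5 from 65140922 to 65141615 (fold 28.0 ± 2.49, SD, n = 4) and, as in Cas9 cells, chromosome 1 from 59758309 to 59758715 (7.20 ± 0.853) and from 197062514 to 197063202 (25.0 ± 2.02). The strongest losses were chromosome 15 from 38978186 to 38978565 (7.70 ± 1.47, SD, n = 2), chromosome 1 from 173400433 to 173400736 (8.89 ± 0.861) and chromosome 19 from 35536698 to 35537132 (11.4 ± 1.79). Of the regions gained in the knockout, 1065 (54.3%) were also gained in Cas9 cells, where independent lists would share 154. The 2 comparisons have no library in common. The 1065 made up 23.9% of the 4455 regions gained in Cas9 cells. Of the 4455, 38.2% had a peak in all 4 knockout direct libraries. With the knockout libraries split otherwise, at most 51 regions were shared, and with the Cas9 libraries split otherwise at most 20. The other splits separated fewer regions and list lengths were not matched, so a smaller overlap was in part given in advance. Losses shared 24 regions against 1.80 for independent lists, and 3 and 2 regions changed in opposite directions. The real split separated 2241 regions against at most 1172 in the other 14, a share of 6.67% that is the smallest 15 splits allow. Gains rose to 4160 without knockout alone replicate 2, and losses to 814 without knockout direct replicate 1 and to 2591 and 1273 without knockout alone replicates 1 and 2. The direct minus alone difference in peak number was not shown to differ between genotypes (5791 more peaks in Cas9 cells, permutation p = 0.295, n = 2 to 4 per group).

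The regions gained in Cas9 direct co-culture were next read in libraries that took no part in choosing them. Regions with a peak in 2 Cas9 direct libraries and none in the Cas9 libraries cultured alone had a peak in 71.4% ± 18.2 of cases in the held-out direct library (SD, n = 3). In knockout direct co-cultures the share was 58.2% ± 6.84 (SD, n = 4), in transwell co-cultures 20.1% ± 9.30 (SD, n = 3) and in knockout cells alone 15.7% ± 4.52 (SD, n = 2). Every knockout direct library lay above every transwell library, with a difference of 38.1 percentage points and a two-sided exact permutation p of 0.0286, the smallest for n = 4 and 3 (adjusted p = 0.12 over 9 tests). The knockout mean lay 13.2 points below that of the held-out Cas9 libraries (exact permutation p = 0.257, n = 3 and 4, adjusted p = 0.289), but each held-out library was read on its own set of 5263 to 8797 regions, which adds to their spread. On the same set, the held-out Cas9 library lay above a knockout library in 11 of 12 comparisons, with a mean gap per set of 3.92 to 19.7 points, and in 12 of 12 with the 43859 strongest peaks. These comparisons share libraries, were made after the data were seen and were not given a p-value. With the first AML label only, where regions were chosen on 1 direct library (13695 and 14694 regions), the gap was 21.6 points, from 62.1% ± 3.09 in held-out Cas9 libraries to 40.5% ± 8.93 in the knockout (SD, n = 2 each), with an exact permutation p of 0.333 that is the smallest possible. Transwell and knockout cells alone differed by 4.40 points (exact permutation p = 0.9, n = 3 and 2). When the regions were chosen on knockout direct co-cultures in the same way, held-out knockout libraries had a peak in 78.6% ± 4.45 (SD, n = 4) and Cas9 direct libraries in 86.3% ± 0.659 (SD, n = 3), a choice made after the data were seen (a difference of 7.62 points, exact permutation p = 0.0571, adjusted p = 0.12). On the same set, the held-out knockout library lay above a Cas9 direct library in 0 of 12 comparisons. With the 43859 strongest peaks this was again 0 of 12, at 48.9% ± 7.48 in held-out knockout and 59.3% ± 2.29 in Cas9 direct libraries. As deposited, Cas9 libraries cultured alone had a peak in 18.7% ± 13.5 of these regions (SD, n = 2) and transwell libraries in 28.3% ± 13.5 (SD, n = 3). Cas9 direct libraries thus had the higher mean share with either choice of regions. Read in the strongest 43859 peaks of each library, the first shares were 41.4% ± 13.8, 30.4% ± 3.33, 12.0% ± 0.204 and 7.35% ± 0.109 in the same order. There every transwell library (at least 11.8%) lay above both knockout libraries alone (at most 7.42%), unlike in the lists as deposited. No test of that difference was run.

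**Figure D3:**
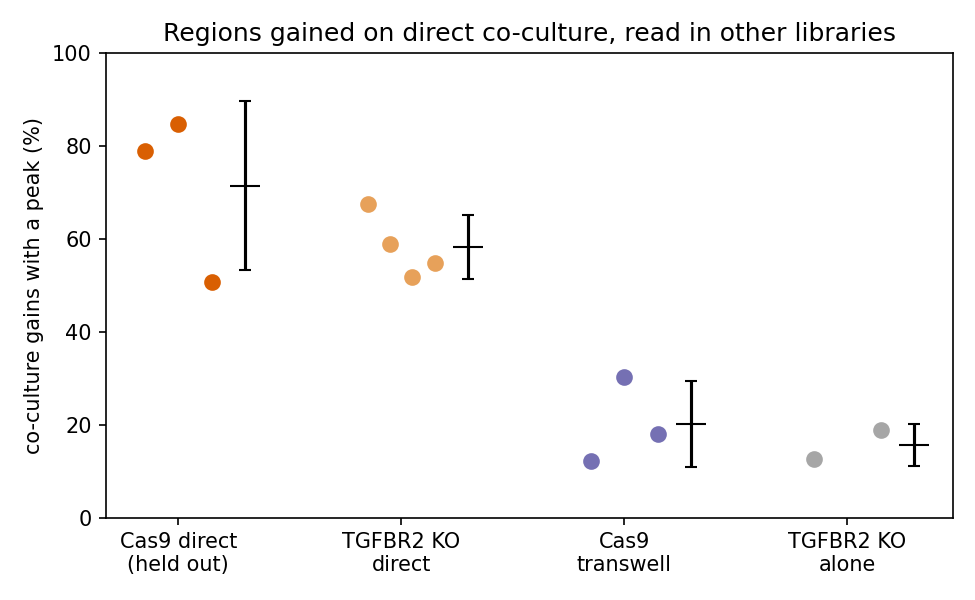
Percent of the regions gained in direct co-culture of Cas9 cells that had a peak (vertical axis) in libraries of 4 groups (horizontal axis); points are libraries, and black lines and bars are means and SDs. Knockout direct libraries average 58.2% and transwell libraries 20.1%.

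Across all libraries, any co-culture against culture alone separated 40 gained regions (10 libraries) from 11 lost (4 libraries), 78.4% gained, or 26 and 73 with equal list lengths, 26.3% gained. Those expected above the limit of every library without the peak were 11 and 1. Gained in all 10 co-cultures were, first, chromosome 1 from 59758309 to 59758715 (fold 6.27 ± 1.48, SD, n = 10), chromosome 11 from 64068464 to 64068817 (2.87 ± 0.577) and chromosome 2 from 17827144 to 17827764 (12.0 ± 3.71). Lost in all 10 were chromosome 15 from 38978186 to 38978565 (7.19 ± 1.07, SD, n = 4), chromosome 5 from 55908542 to 55908974 (10.5 ± 2.29) and chromosome 18 from 14100439 to 14101261 (8.41 ± 1.21). Fisher's exact test per region with Benjamini-Hochberg adjustment called 0 of 89504 regions, with 990 higher and 213 lower at an unadjusted p under 0.05. With equal list lengths it called 0 of 63534, with 484 higher and 799 lower at an unadjusted p under 0.05, a balance that the equal lengths help to set. The lowest unadjusted p of this exact test, 9.99e-04, belongs to regions that separated the groups fully and is the smallest possible here. Adjusted over so many regions, a call would need very many such regions, so 0 calls do not show that no region differed. Gains were 112 without Cas9 transwell replicate 1, 96 without Cas9 alone replicate 2, and 74 and 87 without knockout alone replicates 1 and 2; losses were 17 without transwell replicate 2, 34 and 19 without Cas9 alone replicates 1 and 2, and 21 without knockout alone replicate 1.

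A comparison added after the planned ones were seen set the 7 direct libraries against the 7 without contact. It found 636 regions with a peak in all 7 direct libraries and none of the others, and 3 with the reverse; with equal list lengths the numbers were 440 and 68, or 86.6% gained against 99.5%. Only 41 of the 636 gains (6.45%) and 1 of the losses were expected above the limit of every library without the peak. Knockout direct replicates 2 and 4 held 8029 and 7122 regions missing from transwell replicate 2, with 8586 and 9531 the other way. All other pairs of the same NK source had more regions in the direct library. Its strongest gains were chromosome 2 from 9692602 to 9693180 (fold 5.72 ± 0.920, SD, n = 7) and from 204751389 to 204751923 (10.5 ± 1.17), and chromosome 1 from 32356703 to 32357285 (11.6 ± 2.23). The 1 strongly lost region was chromosome 6 from 15327508 to 15327768 (4.76 ± 0.619, SD, n = 7). Direct libraries had 58350 ± 3415 peaks and the others 49591 ± 4880 (SD, n = 7 each, two-sided exact permutation p = 0.00233). The height of regions shared by all libraries, over the background, was 72.0 ± 5.89 in direct libraries against 64.7 ± 6.32 (SD, n = 7 each, exact permutation p = 0.0449). This call was lost in the paired analysis within NK source (exact permutation p = 0.0522), and passed the threshold in 4 of the 14 repeats that left out 1 library. The Fisher test with Benjamini-Hochberg adjustment called 0 regions (lowest adjusted p = 0.0816), with 3464 higher and 102 lower at an unadjusted p under 0.05. With equal list lengths this exact test also called 0 (lowest adjusted p = 0.0729), with 1747 higher and 895 lower. Regions that separate the 2 sets fully have the smallest p possible here, 5.83e-04 by this exact test, before adjustment. Their adjusted p was set by how many such regions there were among all regions entered, so 0 calls do not show that no region differed. The 3 losses became 5, 8 and 5 without Cas9 direct replicate 2 and knockout direct replicates 1 and 4.

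The similarity of the peak sets, as the Jaccard index of covered base pairs, ran from 0.567 to 0.756 over all pairs of libraries. Pairs within the 7 direct libraries or within the 7 without contact averaged 0.709, and pairs between the 2 sets 0.668 (one-sided exact permutation p = 5.83e-04, n = 7 each, the smallest possible). This grouping was chosen after the data were seen, and its p-value was not adjusted. Permuted within NK source, the exact permutation p was 8.16e-04, also the smallest possible. Both sets hold libraries of the same 2 NK sources, so n counts libraries and not sources. Cas9 direct and transwell libraries had 0.697 within and 0.634 between groups (exact permutation p = 0.1, n = 3 and 3, the smallest possible, adjusted p = 0.233 over 7 comparisons). Between the genotypes, pairs averaged 0.726 within and 0.740 between groups in cells cultured alone (exact permutation p = 1, n = 2 and 2). Every within-group pair there crosses NK sources. Pairs between the groups stood at 0.751 and 0.756 within a source, and at 0.716 and 0.737 across sources, so this comparison mixes genotype with source. In direct co-culture, pairs of libraries averaged 0.716 within and 0.707 between the genotypes, a difference that did not pass the test (exact permutation p = 0.2, n = 4 and 3). The most alike pair was Cas9 alone replicate 2 and knockout alone replicate 2, at 0.756.

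**Figure D4:**
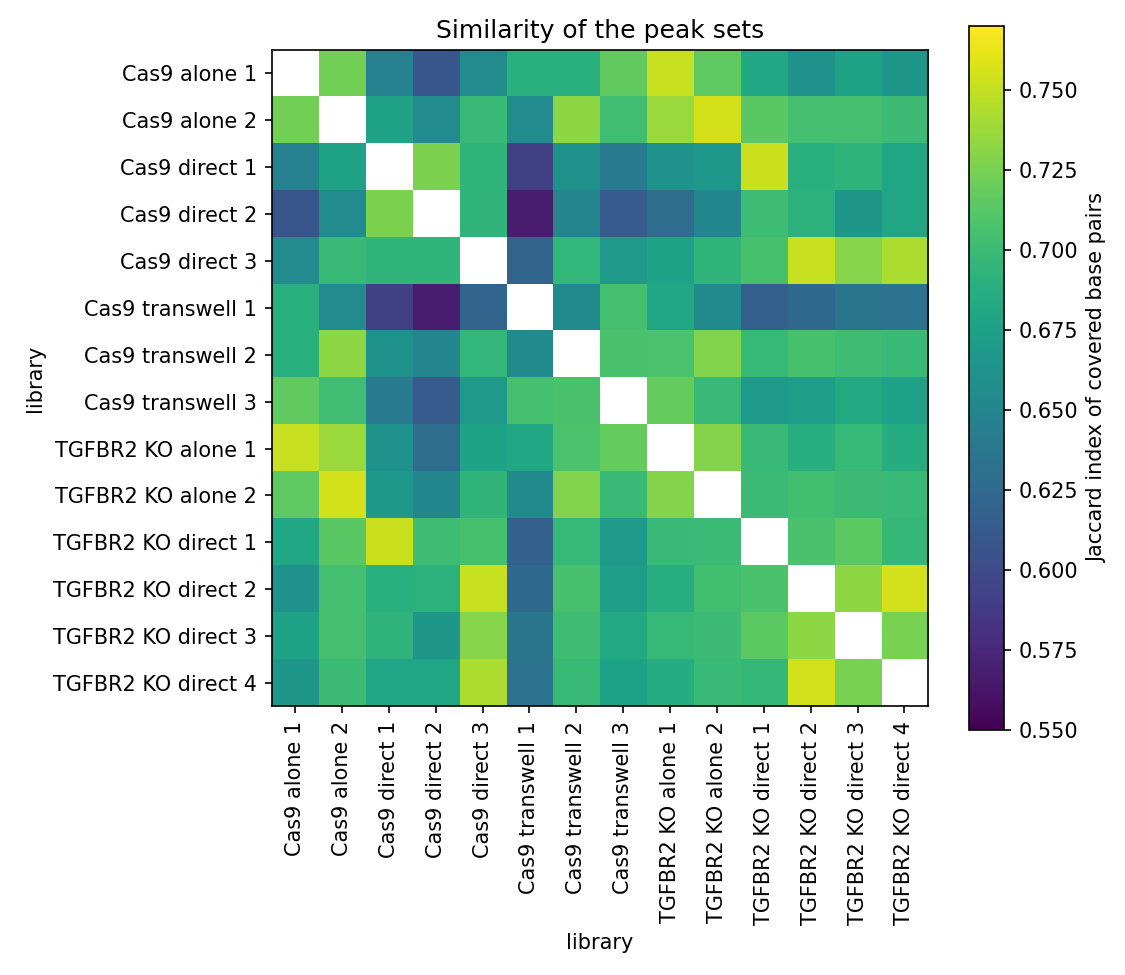
Jaccard index of covered base pairs (colour) for each pair of the 14 libraries (both axes); the diagonal is blank. Values run from 0.567 to 0.756, and pairs that share contact or its absence average 0.709 against 0.668 for the other pairs.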

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

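The tests on AML cells, on background coverage, on the sample labels, on libraries that took no part in choosing regions, and on splits of the direct against no contact comparison were chosen after the results they bear on were seen. The tests on other splits of the planned comparisons, on expected heights in the libraries cultured alone and in transwell, and on enrichment were set before, except that the share of splits that decides was written down after. Knockout direct replicate 4 had 38 peaks on unplaced contigs where the other 3 libraries of its group had 43 and 44, a gap that stood apart among 4 values, and chance gives such a gap in about 1 of 20 groups.

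Regions gained in direct co-culture of Cas9 cells could come from lower depth or enrichment of the libraries cultured alone. If the 4455 regions had been as tall there as in the direct libraries, 44.1% of them would be expected above the limit in Cas9 alone replicate 1 and 62.7% in replicate 2. The bound set in advance was 50% in both, so the result fell on either side of it, and lower depth cannot be told apart for the regions not expected; that the least direct height was used had not been part of that bound. Other sets of 5263 to 8797 regions, chosen with 1 Cas9 direct library held out, were read where they were expected above the limit of the library read. There, knockout libraries cultured alone had a peak in at most 20.8% on average over the sets (23.4% in a single set) against at least 59.3% in held-out Cas9 direct libraries, which argues against depth for the expected regions of these sets. AML cells carried into the direct libraries stay open: the AML labels separated 418 regions of the 7 direct libraries, the fifth most of 35 splits with a median of 192, and regions that both AML samples share would not show in this test.

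Few gains in transwell co-culture may come in part from lower depth. Only 15.1% of the direct co-culture gains would be expected above the limit in Cas9 transwell replicate 1 and 34.6% in replicate 3, against 71.1% in replicate 2, so for the regions not expected depth remains a candidate explanation. Of those expected, 16.9%, 35.2% and 25.3% had a peak in transwell replicates 1, 2 and 3. In the sets chosen with 1 Cas9 direct library held out, transwell libraries had a peak in at most 32.1% of the expected regions on average over the sets (36.2% in a single set), against at least 59.3% in held-out Cas9 direct libraries, which depth alone would not give. What accounts for that part stays open: no test here separates contact itself from carried AML cells, which would take a library of AML cells alone, and none was at hand.

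Among the 7 direct libraries, the split that separated the most regions, 1840, put Cas9 direct replicates 1 and 2 with knockout direct replicate 1. All 3 carry the first AML label, as does knockout direct replicate 2 on the other side, so a part of the AML label in this split is not ruled out. No split by a whole label came near, with 651 at most, and background coverage does not set the 3 apart, as their lowest of 1.52 reads lies below the 1.82 of another library. Enrichment may account for it: the height of shared regions over background was at least 73.6 in the 3 libraries and at most 71.4 in the other 4, a narrow gap. The 3 libraries also had the longest lists, with at least 60123 peaks against at most 56852 in the other 4. No biological explanation of this split was tested beyond the labels.

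For the 7 direct libraries against the 7 without contact, 1 of 100 splits, the real one, gave 639 regions, and the highest other gave 13. No other split drawn came near. This grouping was chosen after the same data were seen, so the share of splits cannot exclude chance. For co-culture against alone, 2 of 100 splits gave at least the real 51 regions, the highest other 63. For knockout against Cas9 in direct co-culture, 6 of 35 splits gave as many as the real 390, so chance was not excluded, and the highest other of 1840 points to a structure of the libraries other than genotype. For direct against transwell co-culture, only 1 of 10 splits gave the real 3650 (highest other 876), and 10 splits are too few for a share under 0.05.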

How the results depend on the processing

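The depth-checked counts, the comparison of direct co-culture with no contact and its alternatives, the reverse choice of regions, the comparison of genotypes on the same set of regions, the chromosome shares among variable regions and the splits on equal list lengths were chosen after seeing the data; the other alternatives were planned. Gains outnumbered losses in direct co-culture against alone and against transwell under every alternative run. For transwell against alone, losses outnumbered gains with equal list lengths, at a −log10 q of at least 5 (523 gained, 594 lost), with 50% cover (735 and 875), and without Cas9 transwell replicate 2 or Cas9 alone replicate 1. The same held for all co-cultures with equal list lengths, and for the knockout alone without Cas9 alone replicate 1, while depth-checked counts of the knockout alone were equal. With equal list lengths, which pull both numbers towards balance by construction and so cannot tell their direction, gained and lost regions were 2091 and 1542 for direct against alone in Cas9 cells, 1850 and 909 for direct against transwell, 1035 and 875 for direct against alone in the knockout, and 26 and 73 for all co-cultures. Gains of the knockout alone came to 550, losses of the knockout in direct co-culture to 152 and losses against no contact to 68. Kept to regions expected above the limit of every library without a peak, gains and losses were 1963 and 185 (direct against alone, Cas9), 466 and 67 (transwell against alone), 210 and 210 (knockout alone), 26 and 76 (knockout, direct), 993 and 86 (direct against alone, knockout), 11 and 1 (all co-cultures) and 41 and 1 (direct against no contact), with 466 and 172 for direct against transwell; fewer regions enter by construction, and depth limits this most where transwell libraries lack the peak (6.45% of the gains of direct against no contact and 13.6% of those of direct against transwell were expected, and 44.1% of those of direct against alone). With the first AML label only, fewer libraries have to match, and the numbers were 8797 and 683 (direct against alone, Cas9), 8287 and 923 (direct against transwell), 956 and 2873 (knockout, direct), 3902 and 526 (direct against alone, knockout), 95 and 18 (all co-cultures), 1519 and 9 (direct against no contact) and 1372 gains for transwell. Cover of 50% of a region gave 25 gains for all co-cultures and 6 losses against no contact, and a −log10 q of at least 5 gave 1 such loss. Leaving out 1 library, which loosens the rule, gave gains of 5046 to 8930 and losses of 553 to 2954 (direct against alone, Cas9), 1081 to 2871 and 728 to 4156 (transwell against alone), 3651 to 7555 and 359 to 738 (direct against transwell), 1360 to 4907 and 1217 to 4555 (knockout alone), 155 to 342 and 407 to 2194 (knockout, direct), 2324 to 4160 and 334 to 2591 (direct against alone, knockout), 42 to 112 and 11 to 34 (all co-cultures), and losses of 3 to 8 against no contact. The share of direct co-culture gains with a peak fell with equal list lengths to 41.4% in held-out Cas9 direct libraries, 30.4% in knockout direct and 7.35% in knockout alone libraries, and with the first AML label only to 62.1% in held-out Cas9 direct, 40.5% in knockout direct and 10.9% in knockout alone libraries; this setting also chose the regions on 1 direct library in place of 2, and the share of each change in the fall was not separated. The peak number difference of transwell and alone, 944, became -96.8 at a −log10 q of at least 5 and ran from -3823 to 5710 with 1 library left out, negative without Cas9 transwell replicate 2 (-2554) and Cas9 alone replicate 1; that of the knockout alone ran from -3085 to 6448, negative without knockout alone replicate 2 (-626) and Cas9 alone replicate 1. For all co-cultures it ran from 4324 to 7513, and passed the threshold without Cas9 transwell replicate 1 (exact permutation p = 0.0168). The within minus between similarity of transwell and alone, -2.09e-04, became 0.00861 with equal list lengths and 0.00244 on merged regions; the cause was not tested. Permutation within NK source as a block, the paired analysis, ended 1 call: the difference of 7.33 between direct and no contact in the height of shared regions over background went from an exact permutation p of 0.0449 to 0.0522. With 1 library left out, this difference ran from 5.88 to 9.48, with an exact permutation p from 0.00466 to 0.0897. No other call for peak number, similarity or splits changed with the block, and the Cas9 direct against alone difference of 11992 peaks had an exact permutation p of 0.167, the smallest its 6 arrangements allow. The alternatives set for motif, gene list and promoter results were not run.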

Other observations

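Gains in direct co-culture were unevenly spread over chromosomes, a view taken after the data were seen. Regions with a peak in all 14 libraries cannot be gained and made up 45.6% of those on chromosome 19 against 36.5% of all regions, so shares were taken among the other 56843 regions. On chromosome 19, 88 of 2283 such regions (3.85%) were gained in Cas9 cells against 7.84% over all chromosomes (Fisher's exact test, adjusted p = 7.60e-14 over 23 chromosomes). By the same exact test, the knockout had 50 gains there (2.19% against 3.45%, adjusted p = 0.00995), and the comparison of direct co-culture with no contact 8 (0.350% against 1.12%, adjusted p = 0.00149). In Cas9 cells, chromosomes 20 and 22 were also lower, at 6.19% and 5.41%, and chromosomes 2, 3 and 6 higher, at 8.87%, 9.18% and 9.84% (exact test, adjusted p = 1.64e-04 for chromosome 6 and up to 0.0402 for the others). In the knockout, chromosome 10 was higher, with 118 of 2621 (exact test, adjusted p = 0.0419), and no chromosome other than 10 and 19 passed there, or other than 19 against no contact. Taken among all regions, chromosomes 4, 5, 8 and 17 also passed in Cas9 cells and chromosome 17 in the knockout, so these calls depended on which regions were counted. The 56843 regions still include those with a peak in 1 library, which cannot be gained either. This limit therefore remains for the calls that passed. Regions are not independent replicates, so these p-values compare the regions of these libraries.

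Single windows of 1 Mb stood out little. Of 2585 windows with such regions, 0 passed the Benjamini-Hochberg adjusted hypergeometric test for Cas9 gains (121 at an unadjusted p under 0.05) and 1 for knockout gains (81 unadjusted). The latter was chromosome 6 from 133000001 to 134000000, with 5 of 10 regions gained (exact hypergeometric test, adjusted p = 0.0275). The leading windows of Cas9 gains were on chromosome 2, from 204000001 to 205000000 with 13 of 52 regions gained and from 69000001 to 70000000 with 12 of 46, both at an adjusted p of 0.213.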
